A study of Sebastes schlegelii with 6 samples.

How the data were processed

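RNA was taken from whole liver, so transcripts of every cell type in the organ are mixed. Libraries were poly(A)-selected, strand-marked (TruSeq Stranded mRNA) and sequenced as paired ends on an Illumina instrument, per the labels' protocols. Trimmomatic, HISAT2, Cufflinks and HTSeq are named in the submitters' processing notes, with no versions, roles or settings. The genome build is not given in the sources used here, and no reference genome was used. Whether counting used the strand is not given either, so overlapping and antisense genes, and near-identical copies, may share reads.

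The authors' deposited counts are whole numbers per gene and library, not normalized. The authors' deposited FPKM values equal the count divided by the column total and by a fixed length per gene, on the FPKM scale; 99.995% of the lengths recovered this way were within 0.01 bases of a whole number, and all were multiples of 3, so they are coding lengths. The authors' deposited comparison holds a fold change, a ratio of starved over fed, and a q-value per gene, with the test not given. Its direction was checked on the FPKM values, whose group ratio had the same sign for 96.8% of genes. The deposited read statistics give percent of bases at Q30 and GC, and a count of reads by alignment class, per the file headers. Genes carry the deposited symbol or product name, many shared by several genes; 1662 of 19303 had no symbol.

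Samples were grouped as fed or starved from their titles. The title codes share only 1 letter between groups and no numbering, so nothing pairs the samples. Replicates were compared before use: the chi-square per degree of freedom of their counts lay between 36.2 and 162 within groups, so no pair was as close as repeat counts of 1 library would be.

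Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr at its defaults kept 13338 genes, followed by TMM scaling, robust dispersion and the quasi-likelihood F test, starved minus fed, with Benjamini-Hochberg adjustment and calls at an adjusted p under 0.05. CPM values, counts scaled to a common library size, use the TMM factors. A fold against a group with 0 counts is a bound against 3 counts over the group, and 1 to 3 counts are given as a ratio with a 95% exact interval; reads without molecular identifiers are not independent molecules, so these cover counting error only. Tests, alternatives, gene lists and the naming rule were fixed before the data were examined.

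The 37 gene lists were matched to symbols and product names, without counts. The rule that accepts paralog endings also takes some related genes, and the lymphocyte list matched 22 genes named CD22. Lists with at least 5 tested genes were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01, with an estimated correlation and fry beside it. KEGG and GO terms of 10 to 500 tested genes were tested one-sided with Fisher's exact test against the tested genes carrying any term of that kind, 4960 for KEGG and 11700 for GO.

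Named genes are the 12 largest rises and 12 largest falls among called genes with an average of at least 3 log2 CPM, groups that do not overlap and an informative name, counting same-named paralogs as 1; the up to 3 called genes of each list with the smallest p; and a set of metabolic and hormone genes. Other list members named beside them were chosen after their values were seen. Some genes that this rule took are not reported here.

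Alternatives were DESeq2 1.42.0 size factors and its Wald test, upper-quartile scaling, limma-voom, other low-count filters, non-robust fits, limma on log2(FPKM + 1) and log2(FPKM + 0.1), the 20 most abundant genes left out, stricter calls, and each library left out in turn. Quality weights per library in limma, counts per list and terms without each library, and a 2-fold requirement in the authors' table were added after seeing the data. The tests were tried on simulated counts first: over 13107 tested genes, with the real spread, 3 of 50 genes changed 2-fold, 27 of 50 changed 4-fold, 41 of 50 changed 8-fold and 48 of 50 changed 16-fold were called, with 6 false calls of 125. In a second simulation of starved against fed over 13081 genes, a proteasome list raised 4-fold was called and 0 other lists were. Simulated genes were drawn independently, whereas the correlation estimated within the real ribosomal protein list was 0.915. The 0 other lists therefore says nothing about false list calls among genes that move together.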

Results

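Livers of Korean rockfish (Sebastes schlegelii), a marine teleost, were profiled by RNA sequencing after 72 days with or without food. There were 3 fed and 3 starved libraries. The count table held 19303 genes, and total counts ranged from 11623356 in fed replicate 1 to 14716282 in starved replicate 3. The series title states that the study asks how this fish responds to starvation. The labels do not say whether the 3 libraries of a group came from separate fish, so the p-values measure the spread between these libraries.

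Fed replicate 1 stood apart from the other 5 libraries. Its log2 CPM values correlated across genes with the other fed libraries at Pearson r = 0.891 and 0.877, against 0.951 between fed replicates 2 and 3. It also had the lowest share of spliced reads among uniquely mapped reads, 41.7% against 50.7% to 53.3% in the other libraries. Values without this library are given beside many of the results that it changes.

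**Figure D1:**
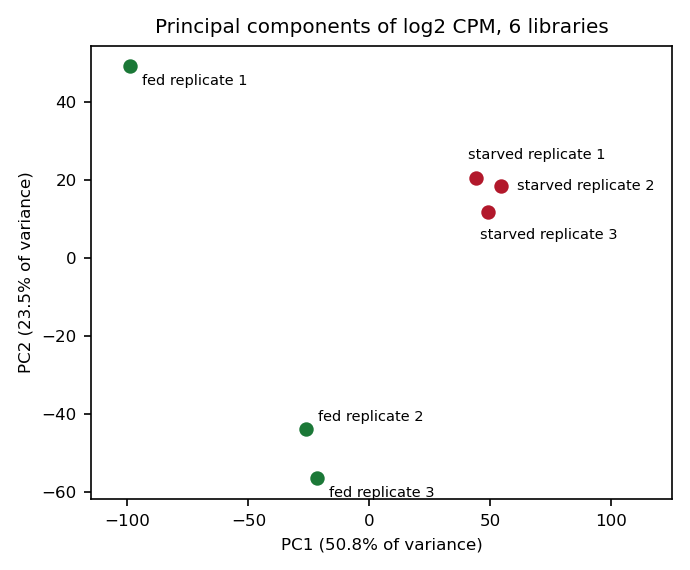
Principal components 1 and 2 of the log2 CPM of the tested genes, one point per library, with the percent of variance on each axis. The 3 starved libraries lie together, and fed replicate 1 lies apart from fed replicates 2 and 3 on both axes.

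The comparison of starved with fed liver asked which transcripts changed with starvation. Among the largest rises were those of ANGPTL4, Igfbp1, Irs2 and Prodh. ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose from 0.645 ± 0.154 to 263 ± 278 CPM (SD, n = 3 per group; edgeR adjusted p = 0.00864). Igfbp1, which binds insulin-like growth factors in plasma, rose from 1.18 ± 0.428 to 447 ± 180 CPM (n = 3 per group; edgeR adjusted p = 0.00119), and Irs2, an adaptor of the insulin receptor, rose 73.9-fold (edgeR adjusted p = 0.00119). Prodh, the first enzyme of proline breakdown, rose 115-fold (edgeR adjusted p = 0.0015). The ANGPTL4 call was lost without fed replicate 1, and its adjusted p ranged from 7.74e-24 to 0.0662 over the alternatives. Another gene named ANGPTL4 went the opposite way, from a mean of 200 to 69.2 CPM, without passing (edgeR adjusted p = 0.166). A second IGFBP1 gene had means of 12.6 and 19.5 CPM and did not pass (edgeR adjusted p = 0.609).

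The naming rule took 8 other genes for their rise. CYP24A1, which inactivates vitamin D hormone, rose from 0.721 ± 1.09 to 200 ± 109 CPM (n = 3 per group; edgeR adjusted p = 0.0102). chac1, an enzyme of glutathione breakdown, had 3 counts or fewer over the fed libraries, and its starved level was 383 times higher by counts (95% exact interval 131 to 1860, counting error only). Another gene named chac1 fell by 1.67 on the log2 scale (edgeR adjusted p = 0.015), a call that ended without any 1 of the starved libraries (adjusted p up to 0.0953). Stc2, Ppm1k, Ptprn, arg2-c, slc25a42 and Slc7a1 had log2 fold changes of 6.15, 6.14, 4.78, 4.58, 4.49 and 4.25 in that order, with edgeR adjusted p from 0.00239 to 0.0216. The calls of Ppm1k, arg2-c and Slc7a1 ended without fed replicate 1 (highest adjusted p over the alternatives 0.0682, 0.0524 and 0.0834). Those of Ppm1k and Slc7a1 also ended without fed replicate 2, starved replicate 1 or starved replicate 3, and that of Slc7a1 without starved replicate 2.

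Among the largest falls were genes of lipid synthesis. fads2, a desaturase of polyunsaturated fatty acids, had 44.5 ± 23.8 CPM in fed liver and no count in any starved library, so it was at least 631-fold lower against a floor of 3 counts over the group (edgeR adjusted p = 0.00467); without fed replicate 1 its call ended (adjusted p = 0.0636). The acyl-CoA desaturase that makes monounsaturated fatty acids fell from 201 ± 74.5 to 1.85 ± 0.242 CPM (n = 3 per group; edgeR adjusted p = 0.00119). mid1ip1b, a regulator of acetyl-CoA carboxylase, fell from 2604 ± 676 to 7.17 ± 4.76 CPM (n = 3 per group; edgeR adjusted p = 0.00339).

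mfsd2ab, a lysophospholipid transporter, had 1 count over the starved libraries, a ratio of 1170 by counts (95% exact interval 209 to 46242). Saa3, an acute phase protein, fell 173-fold and Aoc1, a diamine oxidase, 183-fold (edgeR adjusted p = 0.00467 and 0.00353). LIPG, PDSS1, trmt2b and CKAP2 had log2 fold changes of -7.22, -6.00, -5.73 and -5.59, with edgeR adjusted p from 0.00199 to 0.014. The LIPG call ended without starved replicate 1 (adjusted p = 0.088, the highest over its alternatives; the lowest was 7.33e-08).

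**Figure D2:**
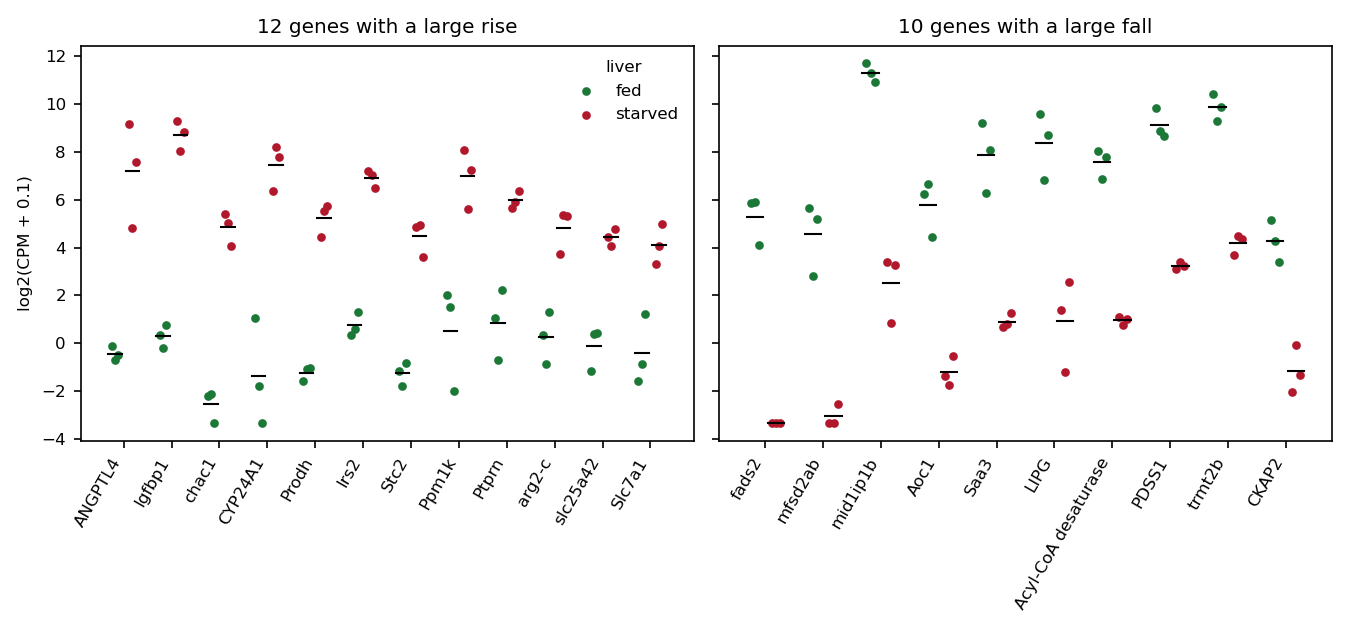
Expression per library of 12 genes with a large rise (left) and 10 with a large fall (right), as log2(CPM + 0.1), fed in green and starved in red; each point is a library and each bar the mean of 3. The groups do not overlap for any of these genes, which the rule for naming them required, and fads2 sits at the bottom of the axis in all starved libraries.

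In all, 688 of 13338 tested genes changed, 291 higher and 397 lower in starved liver (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Groups did not overlap for all 688 of them and for 31.1% of the tested genes, against 10% by chance. The number called rose to 1704 without fed replicate 1 and fell to 232 without fed replicate 2. It fell to 102, 146 and 131 without starved replicates 1, 2 and 3. For called genes an adjusted p introduced by "up to" is the highest over a gene's alternatives; the lowest was 0.00432 (Sult2b1) or smaller for each called gene of the naming rule that is given here. For called list members outside that rule, and for copies, it is the highest over the left-out libraries. A named gene need not stand for all genes of its name. Among the called genes of the naming rule, 32 names had other tested copies, 41 in all, of which 35 did not pass, 4 passed in the same direction and 2 in the opposite one.

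Gene lists were tested as groups with camera, which asks whether a list's genes lie higher or lower than the other genes. With a preset correlation of 0.01 between genes, 14 of 36 lists were called, 8 lower and 6 higher. With a correlation estimated from the libraries 0 were called, and the lowest adjusted p was 0.489. The fry test, which asks whether a list's genes move on balance in 1 direction, called only fatty acid and triglyceride synthesis (adjusted p = 0.0138). Apart from fatty acid and triglyceride synthesis, the direction of each list below therefore rests on the preset correlation, and counts of single genes are given beside it.

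Of 26 tested genes of fatty acid and triglyceride synthesis, 9 fell, 0 rose and 17 did not pass; adjusted over the list alone, 16 fell. The 9 included Acaca, the acetyl-CoA carboxylase of fatty acid synthesis, at 952 ± 257 CPM in fed and 67.6 ± 25.8 CPM in starved liver (n = 3 per group; edgeR adjusted p = 0.00467), with 2 ATP citrate lyase genes, ACLY and Acly, and ELOVL5 and SREBF1. The ELOVL5 call ended without starved replicate 1 or 2, that of SREBF1 without any 1 of the starved libraries, that of ACLY without any library other than fed replicate 1 and that of Acly without any library other than fed replicate 2 (adjusted p up to 0.0729, 0.133, 0.139 and 0.146). With all 6 libraries, the ACLY call ended in both FPKM fits, and that of Acly on log2(FPKM + 1), with limma-voom, with quality weights and with no filter on low counts. Without starved replicates 1, 2 and 3 the number that fell was 3, 3 and 5. FASN, fatty acid synthase, had 149 ± 105 CPM in fed and 39.8 ± 9.41 CPM in starved liver and did not pass (n = 3 per group; edgeR adjusted p = 0.075), but passed with the DESeq2 Wald test and with quality weights (adjusted p from 0.00356 to 0.253 over the alternatives). The list was lower (camera adjusted p = 3.19e-08; adjusted p = 0.489 with an estimated correlation). Its median log2 fold change was -1.35.

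Of 30 genes of cholesterol synthesis, 2 fell, among them IDI1, an isoprenoid isomerase (log2 fold change -2.50; edgeR adjusted p = 0.0304), 28 did not pass, and 7 fell adjusted over the list alone. The IDI1 call ended without fed replicate 3 or any 1 of the 3 starved libraries (adjusted p up to 0.142). In the list, 0 fell without a starved library, 1 without fed replicate 3, and 3 without fed replicate 1 or 2. The list was lower (camera adjusted p = 8.78e-06; adjusted p = 0.823 with an estimated correlation). Of 22 bile acid genes, 3 fell: CYP7A1, the rate-limiting enzyme of bile acid synthesis, went from 91.4 ± 18.3 to 8.29 ± 5.64 CPM (n = 3 per group; edgeR adjusted p = 0.0173), and Hsd3b7 and Nr0b2 had log2 fold changes of -2.45 and -2.63. The CYP7A1 call ended without fed replicate 1, fed replicate 2 or starved replicate 2 (adjusted p up to 0.0888), and those of Hsd3b7 and Nr0b2 without any 1 of the starved libraries (up to 0.137 and 0.174), the former also without fed replicate 2 and the latter without fed replicate 1 or 3 and in both FPKM fits. In all, 1 bile acid gene fell without fed replicate 2 or a starved library, and 2 without fed replicate 3. The bile acid list was lower (camera adjusted p = 0.00393; adjusted p = 0.783 with an estimated correlation), 6 of its genes fell and 1 rose adjusted over the list alone, and its call ended without fed replicate 1 (adjusted p = 0.0558).

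The lists for burning and moving fat were not called with all 6 libraries. Of 32 genes of fatty acid oxidation and ketone bodies, 1 rose and 1 fell (camera adjusted p = 0.232); without fed replicate 1, 4 rose and 2 fell, and without starved replicate 2 the list was called higher (camera adjusted p = 0.00421). CPT1A, which carries fatty acids into mitochondria, rose 21.7-fold in 1 of its 3 tested copies (edgeR adjusted p = 0.00636), while the other copies had log2 fold changes of 1.77 and 1.46 (edgeR adjusted p = 0.117 and 0.066; both passed with the DESeq2 Wald test and the former with quality weights). Of 2 tested genes named for PPARA, the nuclear receptor that drives fat oxidation, 1 fell 42.3-fold (edgeR adjusted p = 0.00339), and the other went the opposite way, from a mean of 23.5 to 72.0 CPM, without passing (log2 fold change 1.62; edgeR adjusted p = 0.0656, and 0.022 without fed replicate 1). Of 16 lipid droplet and lipolysis genes 4 fell and 1 rose (camera adjusted p = 0.48), with Pnpla2, the adipose triglyceride lipase, at a log2 fold change of -3.41. Other genes named Pnpla2 had log2 fold changes of -0.49 and 0.67 and did not pass (edgeR adjusted p = 0.822 and 0.554). LIPA and 1 gene named PLIN2 fell by 2.85 and 3.93 on the log2 scale, and another PLIN2 gene rose by 1.43, a call that ended without fed replicate 2 or any 1 of the starved libraries (adjusted p up to 0.161) and in both FPKM fits. LIPE, hormone-sensitive lipase, was the other gene that fell, while its second copy had a log2 fold change of 1.06 and did not pass. The calls of Pnpla2, LIPA and LIPE, and of the PLIN2 gene that fell, each ended without starved replicate 2 or starved replicate 3 (adjusted p up to 0.0867, 0.11, 0.185 and 0.15). Those of LIPA, LIPE and PLIN2 ended also without fed replicate 2 or starved replicate 1, and those of LIPE and PLIN2 without fed replicate 3; the PLIN2 call ended without fed replicate 1 too. With all 6 libraries, the LIPE call ended with limma-voom and in both FPKM fits. The number of lipolysis genes that fell was then 1 without fed replicate 2 or starved replicate 1, 2 without fed replicate 3 and 0 without starved replicate 2 or 3. Of 28 apolipoprotein and lipid transport genes, FABP3 and FABP7 fell and LPL, lipoprotein lipase, rose 3.58-fold (camera adjusted p = 0.971; the median was 0.15 and the mean -0.38). The FABP3 call ended without any 1 of the starved libraries and that of LPL without any library other than fed replicate 1 (adjusted p up to 0.11 and 0.12).

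Of 41 FOXO and glucocorticoid fasting targets, 9 rose, 4 fell and 28 did not pass; adjusted over the list alone, 13 rose and 6 fell. Those that rose included Igfbp1, both Irs2 genes, Klf15 and GADD45B, whose most changed copy rose 23-fold (edgeR adjusted p = 0.00545). FKBP5, a glucocorticoid-induced chaperone, fell by 3.16 on the log2 scale, a call that ended without any library other than fed replicate 1 (adjusted p up to 0.173), and that of Klf15 ended without any library other than starved replicate 1 (up to 0.171). With all 6 libraries, both calls ended with limma-voom and in both FPKM fits, that of FKBP5 also with no filter on low counts and that of Klf15 with quality weights. The list was higher (camera adjusted p = 0.000838; adjusted p = 0.783 with an estimated correlation). Without fed replicate 2, 5 rose and 1 fell, without fed replicate 3, 9 rose and 1 fell, and without starved replicates 1, 2 and 3, 4, 3 and 4 rose and 0 fell. The call of the less changed Irs2 gene ended without starved replicate 1 or 2 (adjusted p up to 0.0682). FBXO32, a muscle wasting ligase, had a log2 fold change of 0.92 and did not pass (edgeR adjusted p = 0.276).

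Of 30 genes of the growth hormone and insulin-like growth factor axis, 6 rose, 1 fell and 23 did not pass, and 9 rose and 3 fell adjusted over the list alone. Besides Igfbp1 and Irs2, those that rose were IGFBP3, SOCS2 and INSR. SOCS2 and INSR had log2 fold changes of 3.32 and 1.14, and IGFBP3 had no count in any fed library and a mean of 1.66 CPM in starved liver. All 3 calls ended without any library other than fed replicate 1 (adjusted p up to 0.0879, 0.156 and 0.114 for SOCS2, INSR and IGFBP3), and that of INSR also in both FPKM fits. The list was higher (camera adjusted p = 0.0278; adjusted p = 0.823 with an estimated correlation), a call that ended without fed replicate 1 (adjusted p = 0.412), without starved replicate 2, with the stricter filter on low counts and with quality weights. Without fed replicate 1, 8 rose and 6 fell, and 2 or 3 rose without any 1 of the other libraries. igf1 had 225 ± 158 CPM in fed and 80.5 ± 35.6 CPM in starved liver and did not pass (n = 3 per group; edgeR adjusted p = 0.247), but passed without fed replicate 1 and with quality weights, the lowest of its adjusted p values being 0.0179 and the highest 0.575 over the alternatives. The 2 growth hormone receptor genes had log2 fold changes of -0.06 and -0.62 and did not pass, although the latter passed without fed replicate 1 and with quality weights, and the leptin gene had 0.70.

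Of 20 gluconeogenesis and glycogen breakdown genes, PPARGC1A, a coactivator of that programme, rose 12.4-fold (edgeR adjusted p = 0.014) and 19 did not pass (camera adjusted p = 0.163; called higher without starved replicate 2, 0.0442). PCK1, its rate-limiting enzyme, had 3.85 ± 2.15 CPM in fed and 5.12 ± 3.06 CPM in starved liver (n = 3 per group; edgeR adjusted p = 0.733). The 4 genes named for glucose-6-phosphatase had log2 fold changes from -2.04 to 1.97, none of which passed, although 1 of them passed without fed replicate 1 (adjusted p = 0.0449). The PPARGC1A call ended without fed replicate 2, starved replicate 1 or starved replicate 3 (up to 0.0669). Without fed replicate 1, 3 of the 20 genes rose and 2 fell. Among 28 genes of glycolysis and glycogen synthesis 0 rose and 1 fell, while 5 rose without fed replicate 1 (camera adjusted p = 0.233; the median was 0.38 and the mean -0.21). Of 63 amino acid catabolism and urea cycle genes, 6 rose and 1 fell (camera adjusted p = 0.175), the rises including Prodh, arg2-c, gpt2l, tdo2a and IVD, while 11 rose without fed replicate 1, 3 without fed replicate 3 and 2 without any 1 of the other libraries. gpt2l, an alanine aminotransferase, rose 3.79-fold (edgeR adjusted p = 0.0218; up to 0.0978 when 1 library other than fed replicate 1 was left out), and the calls of tdo2a and IVD ended without any of those 5 libraries (up to 0.12 and 0.103).

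3 lists of protein synthesis were called higher with the preset correlation, and few of their genes passed. Fed replicate 1 had the highest mean ribosomal protein level of all libraries, 9.98 log2 CPM against 8.29 and 8.47 in the other fed and 9.37 to 9.92 in the starved libraries. Of 85 cytosolic ribosomal protein genes, 1 rose, rps6 (log2 fold change 1.93; edgeR adjusted p = 0.0398), and 84 did not pass, while 74 rose without fed replicate 1. The rps6 call ended without any 1 of the other 5 libraries (adjusted p up to 0.158), and a more abundant rps6 gene, at means of 613 and 945 CPM, did not pass (edgeR adjusted p = 0.55). The list was higher in both cases (camera adjusted p = 3.44e-08, and 1.27e-30 without that library; adjusted p = 0.823 with an estimated correlation). Of 44 ribosome biogenesis genes 5 rose, among them DDX21, a nucleolar helicase, which went from 75.9 ± 32.7 to 438 ± 52.2 CPM (n = 3 per group; edgeR adjusted p = 0.014), UTP4 and tsr1 (camera adjusted p = 0.00614; adjusted p = 0.823 with an estimated correlation). The list's call ended without fed replicate 2 or starved replicate 1, and those of DDX21, UTP4 and tsr1 without fed replicate 2 or any 1 of the starved libraries (adjusted p up to 0.0674, 0.149 and 0.133), that of UTP4 also without fed replicate 3, and those of UTP4 and tsr1 in both FPKM fits; 3 rose without fed replicate 3 and 0 without fed replicate 2 or a starved library. Of 52 translation genes, 5 rose, all of them initiation factors such as eif2s3 and eif3ea, and EIF4E, the cap-binding protein, fell by 2.56 on the log2 scale (camera adjusted p = 0.00306; adjusted p = 0.823 with an estimated correlation), a list call that ended without fed replicate 2. Without fed replicate 1, 17 of the translation genes rose and 2 fell, and without any 1 of the other libraries 0 rose (adjusted p up to 0.128 for eif2s3 and 0.122 for eif3ea). The EIF4E call ended without any 1 of the starved libraries (up to 0.0549). Another EIF4E gene had means of 35.3 and 35.7 CPM in fed and starved liver and did not pass (edgeR adjusted p = 0.982).

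Of 100 genes of oxidative phosphorylation none passed, and the list's median log2 fold change was -0.52 (camera adjusted p = 0.0446; adjusted p = 0.854 with an estimated correlation). Without fed replicate 1 the direction turned, to a median of 0.19 with the list called higher (camera adjusted p = 0.0235), and 2 of its genes rose. The call also ended without starved replicate 1 or 2 (adjusted p = 0.059 and 0.137), with the stricter filter and with quality weights. None of 40 proteasome genes passed, and their median was -0.59 (camera adjusted p = 0.000387; adjusted p = 0.823 with an estimated correlation). The call ended with quality weights (0.0733) and without fed replicate 1 (0.278), where the median was -0.08 and 1 gene fell.

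Of 46 cell cycle and DNA replication genes, 19 fell, 0 rose and 27 did not pass, and 30 fell adjusted over the list alone. TOP2A, which untangles replicated DNA, went from 20.1 ± 11.7 to 1.3 ± 0.131 CPM (n = 3 per group; edgeR adjusted p = 0.00643). MKI67, a marker of dividing cells, fell 8.04-fold (edgeR adjusted p = 0.00648), and ccnb1, the mitotic cyclin B1, 30.5-fold (edgeR adjusted p = 0.00643); these 3 calls ended without starved replicate 1 (adjusted p up to 0.055). Without fed replicate 1, 18 fell and 2 rose. Without fed replicate 2, 6 fell, and without starved replicates 1, 2 and 3, 2, 5 and 7 fell. The list was lower (camera adjusted p = 2.28e-14; adjusted p = 0.823 with an estimated correlation), with a median log2 fold change of -2.44, and of -1.51 without fed replicate 1.

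Among markers of other cell types, 8 of 21 fibroblast and stellate cell genes fell and 13 did not pass, with 11 lower and 1 higher adjusted over the list alone. col1a2, a chain of type I collagen, went from 116 ± 29.4 to 19.6 ± 3.48 CPM (n = 3 per group; edgeR adjusted p = 0.00545), and the 2 genes named COL1A1 fell by 2.33 and 2.32 on the log2 scale, calls that ended without starved replicate 1 or 3 (adjusted p up to 0.055 and 0.0585). Without fed replicate 2, 4 fell, and without starved replicates 1, 2 and 3, 1, 4 and 1 fell. The list was lower (camera adjusted p = 0.000113; adjusted p = 0.783 with an estimated correlation). Of 12 erythroid genes, hbb2 and an embryonic alpha hemoglobin fell and RHAG, an erythroid ammonium transporter, rose (camera adjusted p = 0.0215; adjusted p = 0.823 with an estimated correlation); the call ended without fed replicate 1 (adjusted p = 0.153), without fed replicate 3, without starved replicate 1 and with quality weights. The calls of hbb2, the alpha hemoglobin and RHAG ended without fed replicate 2, starved replicate 2 or starved replicate 3, and the former 2 without starved replicate 1; those of hbb2 and RHAG ended without fed replicate 3, and that of hbb2 without fed replicate 1 (adjusted p up to 0.141, 0.139 and 0.11). With all 6 libraries, those of hbb2 and the alpha hemoglobin ended with no filter on low counts, and the latter also with limma-voom. alas2, the erythroid enzyme of heme synthesis, had a log2 fold change of -0.62 and did not pass.

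The other marker lists were not called with all 6 libraries. The median log2 fold change was 0.46 over 15 endothelial genes (camera adjusted p = 0.0657; called higher without fed replicate 2, 0.0199, or starved replicate 3, 0.0299), 0.21 over 9 lymphocyte genes (0.617) and 0.22 over 22 macrophage and granulocyte genes (0.892), of which 3 lysozyme C genes fell; the mean of the last list was -0.10. The most abundant lysozyme C gene had 27249 ± 4997 CPM in fed and 6051 ± 1282 CPM in starved liver (n = 3 per group; edgeR adjusted p = 0.0197, and up to 0.118 without fed replicate 2 or a starved library). Of 15 exocrine pancreas genes Prss2 fell by 4.67 on the log2 scale while the list's median was 1.88 (camera adjusted p = 0.578; called higher without starved replicate 1, 0.0251). The mean pancreas level was 4.83 log2 CPM in starved replicate 3 and 3.11 in fed replicate 2, against 1.16 or less in the other libraries. No lysozyme C gene was called without a starved library, and 2 of the list fell without fed replicate 2 or 3. In the bile duct list hnf1ba rose (log2 fold change 1.48; adjusted p up to 0.129 when 1 library other than fed replicate 1 was left out, and not called in either FPKM fit; camera adjusted p = 0.59 for the list), and among adipocyte genes LPL rose and LIPE fell (camera adjusted p = 0.57). The intestine and kidney list had no call (camera adjusted p = 0.347), and 2 skeletal muscle genes were too few to test.

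**Figure D3:**
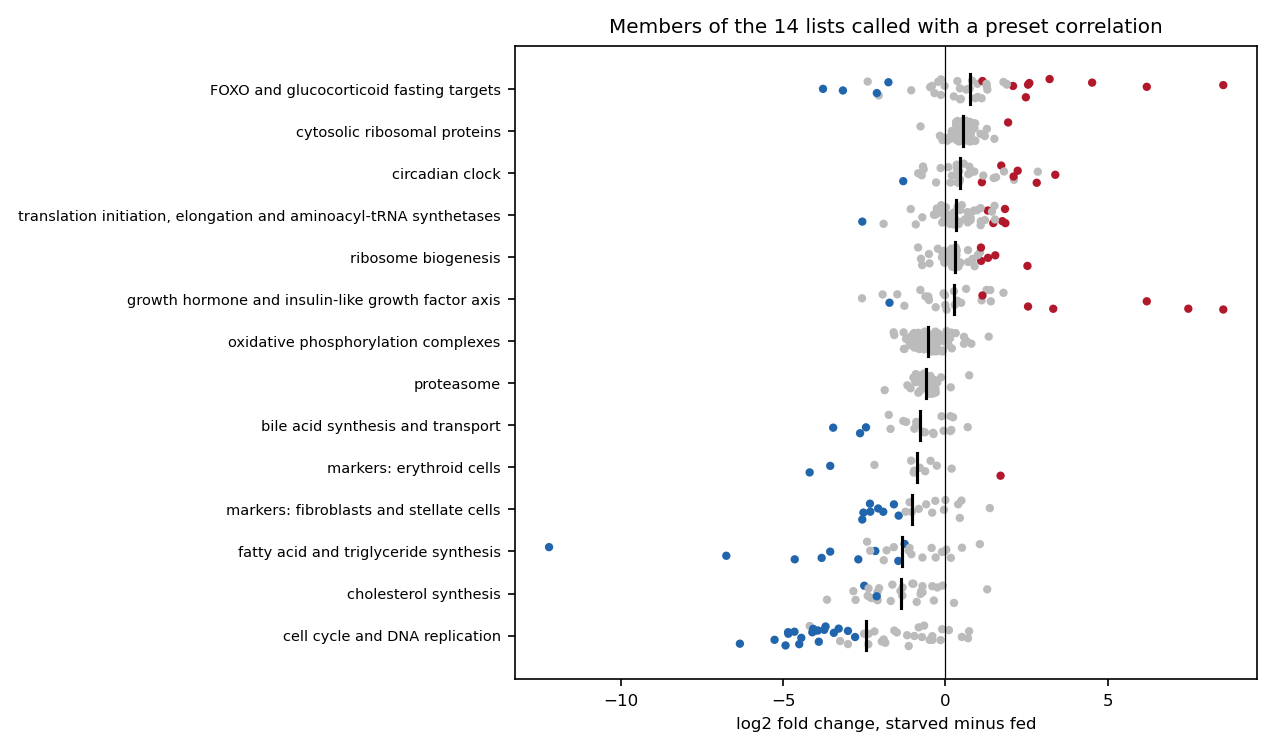
Log2 fold change, starved minus fed, of each member of the 14 lists called with the preset correlation, 1 point per gene and a black bar at each list's median. Red points rose and blue points fell with an edgeR adjusted p under 0.05, and grey points did not pass. Every blue and red point of the cell cycle list lies below 0, and no oxidative phosphorylation or proteasome gene passed.

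Of 35 circadian clock genes 6 rose, 1 fell and 28 did not pass, with 11 higher and 3 lower adjusted over the list alone. The 2 most significant were genes named NR1D2, a repressor of the clock, at 2.73 ± 0.607 and 28.4 ± 3.81 CPM in fed and starved liver for the most changed (n = 3 per group; edgeR adjusted p = 0.00223). nfil3, another clock repressor, rose 7.03-fold, and PER2 fell by 1.30 on the log2 scale, a call that ended without any library other than fed replicate 1 (adjusted p up to 0.161) and in both FPKM fits. Without fed replicate 1, 9 rose and 3 fell, without fed replicate 3, 4 rose, and without any 1 of the other libraries 3 rose; 0 fell without any of those 5. The list was higher (camera adjusted p = 7.78e-05; adjusted p = 0.823 with an estimated correlation).

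Plasma proteins as a list were not called with all 6 libraries (82 genes; camera adjusted p = 0.114), but were called lower without fed replicate 2 (0.00432) or starved replicate 3 (0.0474). LEAP2, hamp and AHSG fell. LEAP2, an antimicrobial peptide made in liver, went from 495 ± 307 to 22.4 ± 8.74 CPM (n = 3 per group; edgeR adjusted p = 0.0117), and hamp, the iron regulator hepcidin, fell 5.11-fold. The calls of LEAP2, hamp and AHSG ended without any 1 of the starved libraries (adjusted p up to 0.0691, 0.116 and 0.19), and that of AHSG also without fed replicate 3 and, with all 6 libraries, in the fit with non-robust dispersion. The 3 other genes named hamp did not pass. Of 20 heat shock genes, 2 genes named as HSP70 protein 1 fell by 4.12 and 3.48 on the log2 scale and SERPINH1 fell too, while DNAJB1 rose and hsp90ab1 rose 5.94-fold, to 7699 ± 2239 CPM (edgeR adjusted p = 0.0131; camera adjusted p = 0.447 for the list). The hsp90ab1 call ended without fed replicate 2 or any 1 of the starved libraries (adjusted p up to 0.0639), and that of the HSP70 gene with the smaller fall without starved replicate 1 (up to 0.0559). The SERPINH1 call ended in the same 4 cases as that of hsp90ab1, and that of DNAJB1 without any library other than fed replicate 1 (up to 0.159 and 0.175). With all 6 libraries, the SERPINH1 call ended in both FPKM fits and that of DNAJB1 with limma-voom. Of 33 cytochrome P450 and conjugation genes, CYP24A1 and CYP1B1 rose and CYP2R1, a vitamin D 25-hydroxylase, and Sult2b1 fell (camera adjusted p = 0.733); the calls of CYP2R1 and Sult2b1 ended without fed replicate 2 or any 1 of the starved libraries, and that of CYP2R1 without fed replicate 3 (adjusted p up to 0.14 and 0.187). The CYP1B1 call ended without each of the 6 libraries (up to 0.186). With all 6, the calls of CYP2R1, Sult2b1 and CYP1B1 ended in both FPKM fits, those of Sult2b1 and CYP1B1 with limma-voom, that of CYP2R1 with no filter on low counts and that of CYP1B1 with quality weights. vtg1, the egg yolk precursor vitellogenin, had 4.76 ± 2.89 CPM in fed and 0.543 ± 0.448 CPM in starved liver (n = 3 per group; edgeR adjusted p = 0.0435), a call that ended in 8 of its 17 alternatives, namely limma-voom, both FPKM fits and those without fed replicate 1, fed replicate 2 or any 1 of the starved libraries (adjusted p up to 0.174; camera adjusted p = 0.232 for its list).

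No call was made for the tricarboxylic acid cycle (camera adjusted p = 0.232), autophagy and lysosome (0.986), endoplasmic reticulum folding (0.347; called lower without fed replicate 2, 0.0435), antioxidant enzymes (0.232) or interferon and antigen presentation (0.605). Within these, Ulk1 and Atg2b, which act early in autophagy, rose 2.68-fold and 2.53-fold, and SRP14 fell by 1.59 on the log2 scale. Each of these 3 calls ended without fed replicate 3 or any 1 of the starved libraries, and those of Ulk1 and Atg2b without fed replicate 2 (adjusted p up to 0.139). With all 6 libraries, those of Ulk1 and Atg2b ended in both FPKM fits. Another gene named Ulk1 went the opposite way, from a mean of 19.2 to 7.27 CPM, without passing (edgeR adjusted p = 0.0589). It passed as lower without fed replicate 1 (edgeR adjusted p = 0.00341). A further ULK1 gene had a log2 fold change of 1.16 and did not pass (edgeR adjusted p = 0.251). In the autophagy list, 3 genes rose and 3 fell without fed replicate 1. Without fed replicate 1 the tricarboxylic acid cycle list was called higher (camera adjusted p = 0.0361), with 5 genes that rose and 1 that fell.

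Terms of the deposited gene annotation gave 54 calls over 5050 term and direction pairs, 35 for genes that fell and 19 for genes that rose (one-sided Fisher's exact test, Benjamini-Hochberg). Cell division led, with 36 of 277 tested genes lower against 7.96 by chance (adjusted p = 1.07e-10, and 0.000223 without fed replicate 1). Fisher's test counts genes as independent, whereas the correlation estimated within the cell cycle list was 0.535. The p-values of terms whose genes move together may therefore be far too small. PPAR signalling, a pathway of lipid-sensing nuclear receptors, had 12 of 65 genes lower (adjusted p = 0.000774; 0.484 without fed replicate 1), among them fads2, CYP7A1, PPARA and PLIN2. The test counts falls alone, so it does not show that the pathway as a whole fell. The second PPARA gene went the opposite way without passing (log2 fold change 1.62). Collagen trimer had 7 of 48 genes lower (adjusted p = 0.0409). On the rising side, regulation of circadian rhythm had 8 of 32 genes (adjusted p = 0.000282) and the eukaryotic translation initiation factor 3 complex 5 of 13 (adjusted p = 0.00211). The collagen trimer and circadian calls ended without fed replicate 2, starved replicate 1 or starved replicate 3, the former also without fed replicate 3 or starved replicate 2 (adjusted p up to 0.874 and 0.114). Cell division was called without a fed library but not without a starved one, PPAR signalling ended also without fed replicate 2 (0.106), and the initiation factor complex was called again only without fed replicate 1; the highest adjusted p of cell division and of that complex was 1. The number of terms fell to 9 without fed replicate 2, and to 6, 12 and 5 without starved replicates 1, 2 and 3. It was 42 without fed replicate 1, where the term Ribosome led, with 76 of 123 genes higher (Fisher adjusted p = 1.2e-55). In that fit a further term, circadian rhythm, was called in the falling direction, with 11 of 45 genes lower (Fisher adjusted p = 0.0168).

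The authors' deposited table gave a fold change for 16166 genes, of which 1534 had a q value under 0.05, 639 higher and 895 lower in starved liver. All 688 genes called here were among those 1534 with the same sign. Both rest on the same 6 libraries, so the overlap is no independent evidence.

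The 10 most abundant genes took 30.1% ± 4.08 of counts in fed and 27.7% ± 1.63 in starved libraries (SD, n = 3 per group; exact two-sided permutation p = 0.5, adjusted p = 0.55 over 11 measures). Between 15962 and 17083 genes had a count in the fed libraries and between 16725 and 16990 in the starved ones (n = 3 per group; exact permutation p = 0.5). Total counts were higher in every starved library (13469708 to 14716282) than in every fed library (11623356 to 13029074; n = 3 per group; exact permutation p = 0.1, the smallest that 3 against 3 allows).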

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

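The tests of the cell cycle and fibroblast pattern, of length bias in the ribosomal protein genes and of a starved liver labelled as fed were chosen only after values they rest on were seen; the other tests were written down before their values were computed. Read statistics outside the count comparison separated the groups. Every starved library lay above every fed library in the share of uniquely mapped read pairs counted in genes (6.57 percentage points higher on average), in GC content (0.937 points), in bases at Q30 (0.337 points) and in spliced reads as a share of all reads (4.39 points). The last depends on its denominator: as a share of uniquely mapped reads the groups overlapped. Each has an exact permutation p of 0.1, the smallest possible here, and an adjusted p of 0.22.

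Fed replicate 1 stood apart from the other libraries, and RNA degradation is a candidate explanation. Its log2 ratio to the other 2 fed libraries fell with coding length (Spearman rho -0.33 across genes, which are not independent replicates), as loss of long transcripts would give. For the other libraries rho lay between -0.09 and 0.09. Those of fed replicates 2 and 3, 0.0788 and -0.0788, mirror each other, so both are 1 comparison that leaves out fed replicate 1. Reads from genomic DNA or unspliced RNA stay open: 158 genes had counts in this library only, fewer than in any other, but those genes lie near the detection floor and so exclude nothing, and its shares of spliced and of counted reads among uniquely mapped ones (41.7% and 61.9%) were the lowest. A starved liver labelled as fed is argued against: on a line from the mean of the other fed libraries (0) to the starved mean (1), over 1687 genes called without it and tested with all libraries, it lay at 0.0834, while the starved libraries placed the same way lay at 0.901 to 0.973. Another kind of mislabelled sample cannot be told apart, since it lay nearer to the other fed libraries for 66.3% of those genes, short of the 80% set as a bound; its correlations with the starved libraries (0.819 to 0.839) were all below those with the fed ones. A difference between fish is untested.

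Cell cycle and fibroblast lists were called lower with the preset correlation, but not with an estimated correlation (adjusted p = 0.823 and 0.783) or with fry (0.098 and 0.0553). A lower share of all non-hepatocyte cells is argued against. Endothelial, macrophage and lymphocyte markers together had a median log2 fold change of 0.25 against -1.04 for the fibroblast list. The 95% bootstrap interval of the former, 0.03 to 0.51, is that of a median over marker genes. It does not measure the spread between libraries. None of the endothelial, macrophage and lymphocyte lists was called with all 6 libraries. Without fed replicate 1 their medians were 0.23, 0.003 and 0.14 in that order, against -0.95 for the fibroblast list. Marker lists outside that test went both ways with all 6 libraries. Erythroid, bile duct, and intestine and kidney genes had medians of -0.88, -0.43 and -0.41, and pancreas and adipocyte genes 1.88 and 0.35. A lower share of some other cell types therefore stays open. Fed replicate 1 alone is argued against as the source of the cell cycle and fibroblast calls. Of the 27 cell cycle and fibroblast members called lower, 25 were called lower again without it. Over all called genes 657 of 688 were called again, so that share is not particular to these lists. The cell cycle median went from -2.44 to -1.51 without fed replicate 1, so the size of that fall depends on this library. Fewer fibroblasts, less collagen expression per cell and less cell division under starvation stay open and untested.

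Ribosomal protein genes were called almost wholly without fed replicate 1, with 74 of 85 against 1; this library lay nearer to the starved mean than to the other fed libraries for 83 of the 85. At least 75 were called without it under upper-quartile and DESeq2 scaling, but these moved the median of all genes by at most 0.00879 log2, so scaling stays open. A length trend between the groups is argued against, since their median log2 fold change without it was 1.35, above all of 1000 random lists matched on coding length and expression (highest 0.25). Length bias of fed replicate 1 is argued against only weakly as the whole cause. The ratio of fed replicate 1 to the other fed libraries had a median of 1.70 over these genes, above all 1000 matched lists (highest 1.31). This rests on 1 library and on genes that move together (estimated correlation 0.915), which genes of random lists need not do. The matched genes themselves had a median of 1.05, so length bias may account for a large part. Whether fed liver has a low or a variable level of these transcripts stays open with 3 libraries.

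The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 688 called genes and the highest other split 0, with 1 of 10 splits giving as many. For terms the values were 54 and 0, which adds nothing, since a split with no called gene can call no term. For gene lists the real split gave 14 and the highest other split 18, and 4 of the 10 splits gave as many.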

How the results depend on the processing

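Terms, composition and counts per list without each library, quality weights and a 2-fold requirement in the authors' table were chosen after seeing the data. The count of 688 genes (291 higher, 397 lower) became 1513 (624 and 889) with the DESeq2 Wald test, 1951 (909 and 1042) with limma-voom quality weights and 110 (45 and 65) at an adjusted p under 0.01, and 189 genes were higher on log2(FPKM + 0.1); the stricter threshold apart, the cause was not tested. Leaving out each library gave 102 to 1704 genes, 50 to 804 higher and 49 to 900 lower; fewer libraries give fewer calls, but without fed replicate 1 there were more. The other settings stayed within 1.5 times, and all 688 genes kept their sign in each alternative that tested them. Called lists went from 14 to 0 with an estimated correlation and 1 with fry, and ranged from 11 to 16 without each library; without fed replicate 1, 9 of the 14 were called again in the same direction and 1, oxidative phosphorylation, in the other. Called terms went from 54 to between 5 and 55 without each library. The difference in the share of the 10 most abundant genes ranged from -4.70 to -0.73 percentage points without each library, against -2.45. Of 80 called named genes, 29 were called in every alternative with an adjusted p, 36 were lost only when a library was left out and 15 in another setting; 2 named genes had no adjusted p from DESeq2. Among uncalled genes, 1 gene for glucose-6-phosphatase turned from -2.04 to a log2 fold change of 2.06 without fed replicate 3 (lowest -4.20 without starved replicate 3), and 1 growth hormone receptor gene, near 0, to 0.35 with limma-voom, 0.33 and 0.36 on log2(FPKM + 1) and log2(FPKM + 0.1), and to 0.30, 0.22, 0.09 and 3.65e-05 without fed replicate 2, fed replicate 3, starved replicate 1 or starved replicate 3 (lowest -0.53 without fed replicate 1); the cause was not tested. The authors' unadjusted p was not run, since the table used here gives q-values; asking also for a 2-fold change in that table gave an overlap of 683 genes against 688. No paired analysis was possible because the title codes share only 1 letter between groups. At this depth and spread, simulated 2-fold changes were mostly missed, with 3 of 50 called.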

Other observations

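The term and gene comparisons here were set out after their values were seen. Long-chain fatty acid-CoA ligase activity had 5 of 13 tested genes lower (adjusted p = 0.0051; 0.0202 without fed replicate 1), namely SLC27A2, ACSL3, ACSL6, Slc27a4 and Acsl4, which activate fatty acids for use or storage. Microtubule motor activity had 9 of 43 genes lower (adjusted p = 0.0016), among them KIF20A, kif22 and CENPE. It shares the KIF23 genes with the cell cycle list, and Kif20b, CENPE and Cenpe with the cell division term, so it is not a separate result. Steroid hormone receptor activity had 7 of 46 genes higher (adjusted p = 0.0109; 0.0142 without fed replicate 1), of which 3 are the NR1D2 genes of the circadian list. Defense response to bacterium had 8 of 48 lower (adjusted p = 0.0119), 5 of them LEAP2, hamp and the 3 lysozyme C genes given before, which was lost without any 1 library (0.508 without fed replicate 1, highest 1). The other 3 terms were called without fed replicate 3, and ended without fed replicate 2 or any 1 of the starved libraries (highest adjusted p 1, 1 and 0.185).

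A pair of genes, CYP24A1 and CYP2R1, was set side by side only after their values were seen. CYP24A1, which inactivates vitamin D hormone, rose by a log2 fold change of 8.32, while CYP2R1, which makes its precursor, went from 161 ± 151 to 8.61 ± 4.76 CPM (SD, n = 3 per group; edgeR adjusted p = 0.0302). The CYP2R1 call ended in 8 of the alternatives, among them both FPKM fits and the fit with no filter on low counts. The others were those without fed replicate 2, fed replicate 3 or any 1 of the starved libraries (adjusted p from 1.63e-07 to 0.14 over the alternatives). No test of the pathway was run.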
